A study of Mus musculus with 37 samples.

How the data were processed

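Gene expression was measured on Illumina bead arrays in total RNA of adult mouse kidneys. The set holds 37 arrays from 25 mice in 12 groups. In the Twist1 line and the Snai1 line, 1 ureter had been tied off (unilateral ureteral obstruction), and the obstructed kidney and the untouched contralateral kidney of each mouse were arrayed, except mouse 5, whose contralateral kidney is not analysed here. Per the labels, the deleted mice carried a ggt-driven cre recombinase and floxed Twist1 or Snai1 (loss of the gene in proximal tubule cells), and the controls of these lines were floxed mice without cre. Cre and deletion therefore went together within each line. The labels give a mixed C57Bl/6 and sv129 background for the Twist1 line and the wild-type mice and a mixed C57Bl/6 and Balb/c background for the Snai1 line. The healthy deleted mice were 26 weeks old and the other mice 10 weeks old. Sex is not in the labels.

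Per the labels, RNA was taken up in Trizol, its quality was read on an Agilent Bioanalyser, and biotin-labelled cRNA was made with an Ambion MessageAmp kit. The submitters' processing notes name GenomeStudio 5.0. Per the file headers, the deposited non-normalised table gives 1 average signal intensity per probe and array, on a linear scale without background subtraction. Beside each intensity the deposited table gives a detection p-value (p_value) against negative control probes. The authors' series matrix holds intensity values that were a linear function of the same array's average signal (r = 1 in every array), with a scale factor of 0.725 to 1.2, column medians of 6.4 to 16.1 and values below 0. The kind of scaling is not stated. Columns matched to no sample numbered 0.

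Probe intensities were background-corrected from the detection p-values and quantile-normalised with neqc (limma 3.58.1, R 4.3.3, offset 16), and are given on the log2 scale. Of 45281 probes, 34885 carried 1 gene symbol, 18 several and 10378 none, and the symbols of 34807 were found in the reference gene table. A probe was kept where its detection p was under 0.05 on at least 3 arrays, which 24544 probes met. Each gene was represented by its kept probe with the highest mean, which left 12866 genes, 12840 of them in the reference table. Where a gene was not detected on any array of a group, its fold is given as at least N-fold, against the lowest signal among the detected probes of each array or the probe's own signal, whichever was higher. For arrays, their number limits the precision. Detected probes per array numbered 16977 to 20682 (37.5% to 45.7%), and raw median signals were 93 to 133.8. Within groups, arrays correlated at r = 0.936 to 0.992 over 39 pairs, and 0 columns were identical.

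A linear model with 12 group means was fitted with limma over all 37 arrays, and 13 comparisons were read from it with moderated two-sided tests and Benjamini-Hochberg adjustment over all genes. The threshold was an adjusted p of 0.05. Adjusted p-values of genes are limma's throughout. In 12 pairs of kidneys given the same mouse number, residuals correlated at 0.171 to 0.63, above those of other mice, and the consensus correlation was 0.233. The main model left the pairing out, and fits with mouse as a fixed or a random replicate block were run beside it. The test was also run on simulated data with 1 residual spread per gene for all groups, independent genes and 200 changed genes among 12866. Obstructed kidneys varied more (score below, SD 0.86 to 1.67, contralateral 0.12 to 0.53), so recovery in them may be overstated. For a log2 change of 1 it recovered 65% of them in the obstruction comparison, 85% and 67% for the deletion of Twist1 and Snai1 in obstructed kidneys, and 72% and 79% in contralateral kidneys. In healthy kidneys it recovered 74% for cre, 76% for Twist1 deletion and 66% for Snai1 deletion. For a log2 change of 2 the shares were 90% to 100%, with 3 to 12 false calls per comparison.

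Before the data were examined, 30 gene lists, the comparisons, the named-gene rule and most alternatives were fixed. The lists, with measured members of those listed, were extracellular matrix (25 of 30), myofibroblast and pericyte (14 of 16), mesenchymal genes of the epithelial-mesenchymal transition (15 of 15) and epithelial junctions (15 of 19). Proximal tubule transporters (24 of 27), proximal tubule enzymes (21 of 26), fatty acid oxidation (20 of 24), mitochondrial respiration (24 of 27), glycolysis (12 of 15) and tubular injury (19 of 21) followed. The cell cycle was covered by G2 and M phase (15 of 27), G1 and S phase (20 of 23) and cell cycle inhibitors with p53 targets (16 of 19). Immune lists were macrophage and myeloid (19 of 23), neutrophil (8 of 12), T and NK cell (12 of 20), B cell (5 of 13), chemokines and cytokines (22 of 23), complement (10 of 16) and the TGF-beta pathway (15 of 19). Lists of other cells were endothelial (17 of 17), podocyte (9 of 12), thick limb and distal tubule (13 of 16), collecting duct (15 of 16), blood (5 of 8) and adipose tissue (6 of 10). Immediate early and handling genes (13 of 15) and sex-dimorphic kidney genes (13 of 15) completed the set. The adrenal gland list (3 of 12) and the list of Y-linked genes and Xist (4 of 5) fell under the smallest size tested, 5 measured members, so 28 lists were tested. Lists share some members, such as Thy1 and Fn1.

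Each list was tested against all other genes with camera from limma, two-sided, at a preset inter-gene correlation of 0.01, adjusted over the 28 lists of a comparison. The test was repeated with the correlation estimated from the data. Of 364 list tests, 101 passed with the preset and 0 with the estimated correlation, and the second adjusted p stands beside each call. Members were counted over all genes tested and adjusted over the list alone. An obstruction score was built per kidney as the mean of the 200 genes that rose most in the controls of the other line minus the mean of the 200 that fell most, and groups were compared by exact two-sided permutation.

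The text names Twist1 and Snai1 in every comparison, then the 10 largest rises and 10 largest falls past the threshold with named symbols. Where fewer than 5 genes passed, it names all of these and the 5 genes with the smallest p, and from each list 3 or 4 members with the smallest p. The alternatives were quantile normalisation without a background step, an offset of 50, the series matrix values, no detection filter, a stricter one (p under 0.01), all kept probes, a fit of the compared groups only, a covariate of Y-linked minus Xist signal, the replicate blocks, both wild-type groups as control, signatures of 50 and 500 genes, and leaving out each array. A slide block was not run, since no header gives the slide.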

Results

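The 37 arrays formed 12 groups. Obstructed kidneys came from 3 Twist1-line controls (mice 1 to 3), 4 Twist1-deleted mice (mice 4 to 7), 3 Snai1-line controls (mice 8 to 10) and 3 Snai1-deleted mice (mice 11 to 13). Contralateral kidneys of the same mice gave 3 arrays per group. Healthy kidneys came from wild-type mice with cre (mice 14 to 16) and without cre (mice 17 to 19), Twist1-deleted mice (mice 20 to 22) and Snai1-deleted mice (mice 23 to 25), with 3 arrays each. The signal at the 25th percentile of raw values was 91.1 to 110.3 in obstructed kidneys, 86.3 to 110.1 in contralateral kidneys and 107.6 to 121.4 in healthy kidneys. Xist was above the Y-linked genes in 8 of 25 mice, and in 12 of 12 mice with 2 arrays both kidneys gave the same reading. It was above them in 1 mouse of every group of the 2 obstructed lines, in 0 of 3 wild-type mice with cre, 1 of 3 without cre, 3 of 3 healthy Twist1-deleted mice and 0 of 3 healthy Snai1-deleted mice.

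Obstruction in Twist1-line controls asked which genes an obstructed kidney expresses differently from the untouched kidney of the same mice. Snai1, a transcription factor that represses epithelial genes, rose at least 1.98-fold (log2 change 1.27, SE 0.27, adjusted p = 0.000282, n = 3 and 3), from 4.73 ± 0.24 (SD) to 6 ± 0.29. Twist1, a transcription factor of mesenchymal cells, differed by 0.48 (SE 0.20, adjusted p = 0.0518) and was detected in 2 of 3 obstructed and 0 of 3 contralateral kidneys. Lcn2, an iron-binding protein released by injured tubules, rose 117-fold (log2 change 6.87, SE 0.57, adjusted p = 7.41e-10) to 13.74 ± 0.78. Pvalb, a calcium-binding protein of the distal convoluted tubule, had a log2 change of -7.52 (SE 1.17, adjusted p = 5.77e-06), from 12.74 ± 0.32 to 5.23 ± 0.69, near background, as it was detected in 2 of 3 obstructed kidneys. Timp1, an inhibitor of matrix proteases, rose 88.2-fold and Aoc1, a diamine oxidase, 76-fold. The other largest rises were those of Vcam1 (51.6-fold), Fcrls (46.1-fold), Scara3 (log2 change 5.31), the collagen cross-linking enzyme Lox (39.1-fold), Cd44 (36.3-fold), the tubular repair factor Sox9 (31.8-fold) and Edn1 (30-fold). In contralateral kidneys Scara3 was detected in 1 of 3 and Timp1, Fcrls and Lox in 2 of 3, so their levels there lie near background and the folds are approximate. The largest falls included the growth factor Egf (43.9-fold, log2 change -5.46, SE 1.01), the gluconeogenic phosphatase G6pc (27.7-fold, log2 change -4.79, SE 0.57), Ttr (-5.78), Dnase1 (-5.37), Ugt3a1 (-5.30), Slc22a22 (-5.19), Klk1b27 (-4.95), Ces1d (-4.78) and Car14 (-4.71). In total 6063 of 12866 genes changed (47.1%), 3425 up and 2638 down, and 2788 of them by more than 2-fold. With the series matrix values 5273 genes passed, 41.9% of them higher against 56.5%, and the median of all genes shifted by -0.175.

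Matrix, injury, macrophage and chemokine genes rose together in these obstructed kidneys. Extracellular matrix genes had a median log2 change of 3.12, with 25 of 25 members up over all genes and 25 adjusted over the list alone, among them Col1a1 (4.80), Mmp14 (4.61), Lox (5.29) and Sparc (3.36) (camera adjusted p = 2.76e-16, 0.1 with an estimated correlation). Tubular injury genes such as Tmsb10 (3.77) had a median of 2.71, with 17 up and 2 neither, and 19 up adjusted over the list alone (adjusted p = 9.38e-10, 0.1 with an estimated correlation). Of 19 macrophage and myeloid genes 17 rose, also adjusted over the list alone, with Mrc1 (3.93), Tyrobp (3.44) and Fcgr3 (4.02) as examples (median 3.40, adjusted p = 1.16e-13, 0.1 with an estimated correlation). Of 22 chemokines and cytokines 21 rose, led by Cxcl16 (2.66), Ccl12 (3.54) and Ccl7 (at least 6.54-fold), with 21 up and 1 down adjusted over the list alone (median 2.36, adjusted p = 9.74e-09, 0.1 with an estimated correlation). In the TGF-beta pathway 12 of 15 genes rose and 14 did adjusted over the list alone, including Tgif1 (1.90) and Tgfb1 (2.02) (median 1.60, adjusted p = 3.4e-06, 0.1 with an estimated correlation).

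Myofibroblast and pericyte genes rose with a median of 1.41 (10 up, 4 neither, 11 up adjusted over the list alone), among them Pdgfra (2.20), Thy1 (4.89) and Pdgfrb (1.91) (adjusted p = 0.000725, 0.221 with an estimated correlation). Mesenchymal genes of the epithelial-mesenchymal transition rose as well, with Vim (2.83), Fn1 (3.39) and Zeb1 (1.27) as examples (median 1.27, 10 up and 5 neither, 11 up adjusted over the list alone, adjusted p = 0.000841, 0.116 with an estimated correlation). G2 and M phase genes such as Cenpa (2.27) and Kif23 (1.65) rose in 13 of 15 cases, also adjusted over the list alone (median 1.30, adjusted p = 0.00213, 0.323 with an estimated correlation). For G1 and S phase, 11 of 20 rose, including Uhrf1 (2.42) and Mcm4 (1.76), and 13 rose and 1 fell adjusted over the list alone (median 0.82, adjusted p = 0.0023, 0.323 with an estimated correlation). Complement genes had 7 up, 2 down and 1 neither, the same adjusted over the list alone, with Serping1 (2.78) and Cfp (2.80) among the rises (median 1.41, adjusted p = 0.0142, 0.137 with an estimated correlation). Endothelial genes had 12 up, 1 down and 4 neither, and 13 up and 2 down adjusted over the list alone, with Cdh5 at 1.83 and Pecam1 at 1.45 (median 0.97, adjusted p = 0.00995, 0.323 with an estimated correlation). Immediate early and handling genes, which also respond to tissue handling, rose in 7 of 13 cases and in 8 adjusted over the list alone, with Junb (3.03), Jun (1.92) and Fos (2.15) among them (median 1.09, adjusted p = 0.0205, 0.323 with an estimated correlation).

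Transport and energy genes of the tubule fell. Proximal tubule transporters had a median of -2.48, with 22 of 24 down and 2 neither, and 22 down and 1 up adjusted over the list alone, among them Slc2a2 (-2.09), Slc13a3 (-4.63) and Slc22a6 (-4.50) (adjusted p = 8.18e-10, 0.1 with an estimated correlation). Proximal tubule enzymes had 17 of 21 down and 18 adjusted over the list alone, with Ass1 (-2.98), Pck1 (-3.50) and Miox (-4.21) (median -2.56, adjusted p = 1.83e-08, 0.1 with an estimated correlation). Fatty acid oxidation genes fell in 19 of 20 cases, also adjusted over the list alone, including Acadl (-1.90) and Acaa1b (-3.25) (median -1.41, adjusted p = 5.63e-11, 0.1 with an estimated correlation). Of 24 mitochondrial respiration genes 23 fell, also adjusted over the list alone, for example Ogdh (-1.53) and Uqcrc1 (-1.03) (median -0.95, adjusted p = 8.43e-11, 0.126 with an estimated correlation). Thick limb and distal tubule genes fell in 9 of 13 cases, also adjusted over the list alone, with Slc12a1 (-2.31) and Fxyd2 (-1.46) (median -1.46, adjusted p = 0.000107, 0.249 with an estimated correlation). Collecting duct genes fell in 9 of 15 cases, also adjusted over the list alone, with Aqp3 (-3.04) and Slc26a4 (-2.80) (median -1.52, adjusted p = 0.000841, 0.149 with an estimated correlation). Sex-dimorphic kidney genes had 4 of 13 down by both counts (median -2.21, adjusted p = 0.025, 0.249 with an estimated correlation).

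The remaining 9 lists did not pass as sets in Twist1-line controls. Their medians were 0.13 for epithelial junctions, -0.23 for glycolysis, 0.83 for cell cycle inhibitors with p53 targets, where Cdkn1a rose by 2.85, 1.11 for neutrophil, 0.57 for T and NK cell, 0.35 for B cell, 0.47 for podocyte and -0.40 for blood genes, and -1.49 for adipose tissue genes, where Lpl fell by 2.23.

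**Figure D1:**
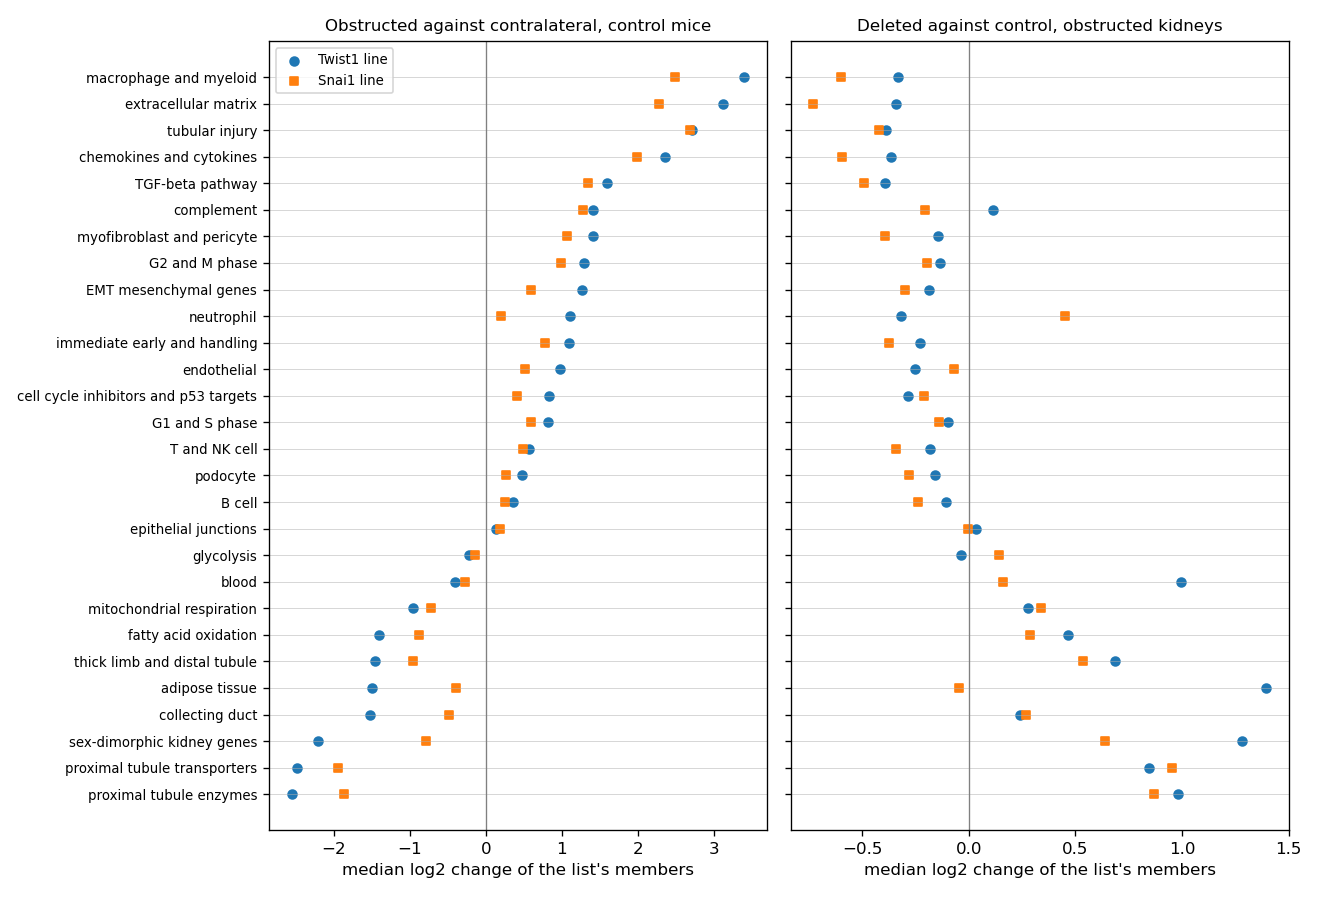
Median log2 change of the measured members of each of the 28 tested gene lists (horizontal axis, log2 units), for obstructed against contralateral kidneys of control mice (left) and for deleted against control mice in obstructed kidneys (right), with circles for the Twist1 line and squares for the Snai1 line. Extracellular matrix genes stood at 3.12 and 2.28 on the left and at -0.34 and -0.73 on the right.

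Obstruction in Snai1-line controls put the same question to a second line. Snai1 rose (log2 change 0.70, SE 0.27, 1.62-fold, adjusted p = 0.0419, n = 3 and 3), from 4.98 ± 0.18 to 5.68 ± 0.35, and Twist1 differed by 0.45 (adjusted p = 0.0854). Lcn2 rose 85.6-fold (log2 change 6.42, SE 0.57, adjusted p = 6.78e-09), Aoc1 58.2-fold, Timp1 35.7-fold, the injury receptor Havcr1 31.1-fold, the neutrophil attractant Cxcl1 29.2-fold and the keratin Krt20 at least 22-fold. Fcrls (5.39), Vcam1 (4.72), Ear3 (4.54) and Sox9 (4.54) completed the 10 largest rises. Pvalb had a log2 change of -6.87 (SE 1.17, adjusted p = 3.98e-05), from 11.66 ± 0.91 to 4.79 ± 0.37, near background, as it was detected in 1 of 3 obstructed kidneys. Cyp2d12 (38.8-fold), the phosphate transporter Slc34a3 (-4.66), Ttr (-4.61), Egf (-4.42), Nccrp1 (-4.41), Spp2 (-4.20), Ces1e (-4.20), Cyp2d26 (-4.02) and Dnase1 (-3.85) also fell. In total 4673 genes changed (36.3%), 2704 up and 1969 down, 1973 of them by more than 2-fold. With the series matrix values 4184 passed, 44.1% of them higher against 57.9%, and the median of all genes shifted by -0.118.

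Matrix genes rose in all 25 cases by both counts, adjusted over all genes and adjusted over the list alone, with Lox (4.18), Col3a1 (2.77) and Col18a1 (1.84) (median 2.28, adjusted p = 3.66e-17, 0.0907 with an estimated correlation). Tubular injury genes rose in 18 of 19 cases by both counts, including Tmsb10 (3.24) (median 2.69, adjusted p = 1.45e-12, 0.0907 with an estimated correlation). Macrophage and myeloid genes rose in 19 of 19 cases by both counts, with Mrc1 (3.73) and Cd14 (4.16) (median 2.48, adjusted p = 4.57e-16, 0.0701 with an estimated correlation). Of 22 chemokines and cytokines 17 rose and 18 did adjusted over the list alone, with Ccl2 (at least 6.65-fold) and Ccl12 (3.49) (median 1.98, adjusted p = 1.83e-09, 0.0701 with an estimated correlation). TGF-beta pathway genes rose in 11 of 15 cases by both counts, with Tgif1 (1.79) and Tgfbr1 (1.49) (median 1.34, adjusted p = 1.41e-05, 0.116 with an estimated correlation). Complement genes rose in 7 of 10 cases by both counts, with Cfp (2.48) and Serping1 (2.35) (median 1.27, adjusted p = 0.00217, 0.0963 with an estimated correlation).

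Myofibroblast and pericyte genes rose in 7 of 14 cases and in 9 adjusted over the list alone, with Pdgfra (1.95) and Thy1 (3.60) (median 1.07, adjusted p = 0.00225, 0.323 with an estimated correlation). Mesenchymal transition genes rose in 8 of 15 cases by both counts, with Fn1 (3.14) and Vim (2.31) (median 0.59, adjusted p = 0.00102, 0.116 with an estimated correlation). G2 and M phase genes rose in 7 of 15 cases and in 9 adjusted over the list alone, with Kif23 at 1.88 (median 0.99, adjusted p = 0.00351, 0.414 with an estimated correlation). In G1 and S phase 8 of 20 rose and 1 fell, and 12 rose and 1 fell adjusted over the list alone, where Uhrf1 rose by 2.12 and Ccnd1, a cyclin of the early cycle, fell by 1.38 (median 0.59, adjusted p = 0.006, 0.414 with an estimated correlation). Immediate early and handling genes rose in 7 of 13 cases by both counts, with Egr1 at 3.34 (median 0.78, adjusted p = 0.0043, 0.323 with an estimated correlation).

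Proximal tubule transporters fell in 20 of 24 cases and in 21 adjusted over the list alone, with Slc5a2 (-3.33), Slc6a19 (-3.43) and Slc2a2 (-1.37) (median -1.94, adjusted p = 8.79e-10, 0.116 with an estimated correlation). Proximal tubule enzymes fell in 12 of 21 cases and in 15 adjusted over the list alone, with Ass1 (-2.42) and Acmsd (-2.80) (median -1.87, adjusted p = 1.9e-07, 0.116 with an estimated correlation). Fatty acid oxidation genes fell in 16 of 20 cases and in 17 adjusted over the list alone, with Hadh at -1.79 (median -0.88, adjusted p = 2.75e-07, 0.116 with an estimated correlation). Mitochondrial respiration genes fell in 20 of 24 cases and in 22 adjusted over the list alone, with Uqcrc1 at -0.99 (median -0.72, adjusted p = 2.48e-09, 0.165 with an estimated correlation). Thick limb and distal tubule genes fell in 7 of 13 cases by both counts (median -0.96, adjusted p = 0.00185, 0.39 with an estimated correlation). Collecting duct genes fell in 5 of 15 cases and in 6 adjusted over the list alone, with Slc4a1 at -2.93 (median -0.48, adjusted p = 0.0236, 0.387 with an estimated correlation). The other 11 lists did not pass, and in neutrophil genes the median was 0.21 while the camera test pointed down (adjusted p = 0.918).

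Both lines changed largely the same genes on obstruction. Of 3926 genes past the threshold in both, 3922 had the same direction, with 2314 up in both against 720 from chance overlap and 1608 down in both against 404. Across genes, which are not independent replicates, the log2 changes of the 2 lines correlated at r = 0.911 (Spearman's rho 0.858), from sets of arrays that share no kidney. With mouse as a fixed replicate block 6234 and 4755 genes passed, and with a random block 6820 and 5535.

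Twist1 deletion in obstructed kidneys asked what loss of Twist1 in proximal tubule cells does to the obstructed kidney. Twist1 itself differed by -0.34 (SE 0.19, adjusted p = 0.508, 4.78 ± 0.25, n = 4, against 5.12 ± 0.38, n = 3) and Snai1 by -0.20 (adjusted p = 0.803). The RNA came from kidneys with all their cells, and it is not known whether the probes lie in the deleted parts of the genes, so these values do not check the labels. Trpv6, a calcium channel of the distal nephron, was 2.25-fold lower (-1.17, SE 0.22, adjusted p = 0.0403, 5.26 ± 0.30 against 6.43 ± 0.34). Selp, the adhesion molecule P-selectin of activated endothelium and platelets, was 2.28-fold lower (-1.19, SE 0.23, adjusted p = 0.0403, 5.35 ± 0.43 against 6.54 ± 0.59). Dcun1d4, a factor of cullin neddylation, was 1.62-fold higher (0.69, SE 0.12, adjusted p = 0.0298, 8.95 ± 0.17 against 8.26 ± 0.31). The transcript 6330403K07Rik was at least 1.62-fold lower (adjusted p = 0.00405) and was detected in 0 of 4 deleted and 3 of 3 control kidneys. Axin2, a Wnt target, had a log2 change of -1.10 and did not pass (adjusted p = 0.0723). These 4 genes, 1 up and 3 down, were all that passed, with 1475 at an unadjusted p under 0.05. The count rested on single arrays: without control mouse 1, 2 or 3 it was 21, 0 or 83, and without deleted mouse 5, 6 or 7 it was 34, 10 or 1. With quantile normalisation and no background step 8 genes passed, 1 of them higher.

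As lists by the preset camera test, proximal tubule, fatty acid oxidation, respiration and thick limb genes stood higher in Twist1-deleted obstructed kidneys, and matrix, injury, macrophage, chemokine and TGF-beta genes lower. No member passed over all genes, and most of these calls depended on mouse 7, as given below. Proximal tubule transporters had a median of 0.84, with 10 of 24 up adjusted over the list alone, led by Slc34a1 (1.12, adjusted p = 0.191) and Slc13a3 (1.99, adjusted p = 0.2) (camera adjusted p = 7.91e-11, 0.251 with an estimated correlation). Proximal tubule enzymes had a median of 0.98, with 5 of 21 up adjusted over the list alone, G6pc at 1.96 and the tubule regulator Hnf4a at 0.77 (adjusted p = 2.92e-08, 0.251 with an estimated correlation). Fatty acid oxidation genes had 0.47, with 8 of 20 up adjusted over the list alone and Acaa1b at 1.57 (adjusted p = 2.81e-11, 0.239 with an estimated correlation). Mitochondrial respiration genes had 0.28 with 0 of 24 adjusted over the list alone (adjusted p = 7.43e-10, 0.296 with an estimated correlation). Thick limb and distal tubule genes had 0.68, with 2 of 13 up adjusted over the list alone and Fxyd2 at 0.68 (adjusted p = 0.000205, 0.413 with an estimated correlation). Matrix genes had -0.34 with 0 of 25 adjusted over the list alone, Timp1 at -1.41 and Tnc at -1.21 (adjusted p = 0.000526, 0.484 with an estimated correlation). Tubular injury genes had -0.39 with Sox9 at -1.04 (adjusted p = 0.00477, 0.484 with an estimated correlation), and macrophage genes -0.33 with Cd14 at -0.85 (adjusted p = 0.0087, 0.526 with an estimated correlation), each with 0 members adjusted over the list alone. Chemokines and cytokines had -0.36, with 1 of 22 down adjusted over the list alone and Cxcl2 at -1.79 (adjusted p = 0.00155, 0.374 with an estimated correlation).

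In the TGF-beta pathway the median was -0.39, with 0 of 15 members adjusted over the list alone and Tgfbr1 at -0.68 (adjusted p = 0.0018, 0.397 with an estimated correlation). T and NK cell genes had -0.18 with 1 of 12 down adjusted over the list alone (adjusted p = 0.0419, 0.451 with an estimated correlation), and endothelial genes -0.25 with 0 of 17 (adjusted p = 0.0433, 0.555 with an estimated correlation). Adipose tissue genes, which report fat around the kidney, stood at 1.39 with 2 of 6 up adjusted over the list alone, Cidec at 2.28 and Car3 at 3.47 (adjusted p = 0.000837, 0.296 with an estimated correlation). Sex-dimorphic kidney genes had 1.28 with 0 of 13 (adjusted p = 0.0081, 0.296 with an estimated correlation). Adipose and sex-dimorphic genes thus moved with the transporters. The other 14 lists did not pass, and for epithelial junctions and glycolysis the median, mean and test differed in sign.

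Mouse 7 stood apart from the other 3 Twist1-deleted obstructed kidneys in several lists. Its mean log2 level was 9.20 against 10.80 to 11.11 for tubular injury and 11.87 against 10.85 to 10.98 for respiration. Without both kidneys of mouse 7, 5 of the 14 list calls were kept: transporters (median 0.55, adjusted p = 8.81e-07), proximal tubule enzymes (0.59, adjusted p = 6.24e-06), fatty acid oxidation (0.33, adjusted p = 2.37e-08), respiration (0.09, adjusted p = 0.00236) and adipose tissue (1.24, adjusted p = 0.00543). The 9 others ended: matrix (-0.13, adjusted p = 0.209), injury (-0.11, adjusted p = 0.861), macrophage (-0.07, adjusted p = 0.371), chemokine, TGF-beta, thick limb, T and NK cell, endothelial and sex-dimorphic genes. Without control mouse 2, 7 of the 14 calls were kept. Those of T and NK cell genes (without mouse 1, 3, 4 or 5), macrophage genes (mouse 1) and endothelial genes (mouse 6) also ended without other single kidneys. Among the calls kept without mouse 7, transporters had a mean log2 level of 7.51 in control mouse 2 against 9.03 and 8.995 in control mice 1 and 3. Deleted mice 4, 5 and 6 had 9.27, 9.00 and 8.775, near control mice 1 and 3. Adipose tissue genes had 9.06 in mouse 5 against 6.35 and 6.75 in mice 4 and 6. No fit left out mice 2 and 7 together, so these kept calls may still rest on single kidneys. Of 35 splits of these mice 18 gave as many lists (14, highest other 19), so chance is not excluded for this number.

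Snai1 deletion in obstructed kidneys asked the same for Snai1. Snai1 differed by -0.36 (SE 0.27, adjusted p = 0.666, 5.33 ± 0.45 against 5.68 ± 0.35, n = 3 and 3) and Twist1 by -0.52 (adjusted p = 0.355). By limma 0 genes passed, with 1421 at an unadjusted p under 0.05 and a smallest adjusted p of 0.101. The 5 genes with the smallest p, none past the threshold, were the lysosomal protease Ctsl (-2.08, 6.47 ± 0.30 against 8.54 ± 0.16), Cd33 (-0.79), Tspo (-0.62), the eosinophil-associated ribonuclease Ear10 (-1.15) and Slc2a6 (-1.69). Without control mouse 8, 9 or 10 the count was 1, 5 or 1, and without deleted mouse 12 or 13 it was 3. Without mouse 7 of the other line, which enters only through the shared estimate of the spread, it was 73 (44 up and 29 down).

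By the preset camera test 16 lists passed, while 0 members did over all genes. Matrix genes had a median of -0.73 with 0 of 25 adjusted over the list alone, Mmp2 at -1.41 and Col1a1 at -0.93 (adjusted p = 7.37e-11, 0.186 with an estimated correlation). Macrophage genes had -0.60 with 0 of 19 adjusted over the list alone and Lyz1 at -0.84 (adjusted p = 4.29e-08, 0.186 with an estimated correlation). Chemokines and cytokines had a median of -0.59, with 3 of 22 down adjusted over the list alone, Tnf at -0.61 and Il18 at -0.70 (adjusted p = 5.33e-06, 0.186 with an estimated correlation). TGF-beta pathway genes had -0.49, with 1 of 15 down adjusted over the list alone and Tgif1 at -0.65 (adjusted p = 2.69e-05, 0.186 with an estimated correlation). Proximal tubule transporters had 0.95, with 8 of 24 up adjusted over the list alone, Slc34a3 at 2.42 and Slc6a19 at 1.72 (adjusted p = 3.29e-12, 0.186 with an estimated correlation). Proximal tubule enzymes had 0.87, with 5 of 21 up adjusted over the list alone, Ass1 at 1.48 and Hnf4a at 0.87 (adjusted p = 2.12e-08, 0.186 with an estimated correlation). Mitochondrial respiration genes had 0.34, with 3 of 24 up adjusted over the list alone and Ogdh at 0.66 (adjusted p = 7.37e-11, 0.186 with an estimated correlation).

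Each of the next lists had 0 members past the threshold over all genes and 0 adjusted over the list alone. Myofibroblast genes had a median of -0.39, with Thy1 at -1.59 (adjusted p = 0.00406, 0.301 with an estimated correlation), and mesenchymal transition genes -0.30, with Snai2 at -0.68 and Vim at -1.13 (adjusted p = 0.00274, 0.186 with an estimated correlation). Tubular injury genes had -0.42, with Krt20 at -1.01 (adjusted p = 0.000592, 0.313 with an estimated correlation), and T and NK cell genes -0.34 (adjusted p = 0.00427, 0.21 with an estimated correlation). Immediate early genes had a median of -0.38, with Fos at -1.07 (adjusted p = 0.0243, 0.357 with an estimated correlation). Fatty acid oxidation genes had 0.29 (adjusted p = 0.000554, 0.301 with an estimated correlation) and glycolysis genes 0.14 (adjusted p = 0.0209, 0.301 with an estimated correlation). Thick limb and distal tubule genes had 0.54, with Pvalb at 2.92 (adjusted p = 0.00173, 0.345 with an estimated correlation), and collecting duct genes 0.27, with Slc4a1 at 1.56 (adjusted p = 0.0131, 0.301 with an estimated correlation). Adipose tissue genes had a median of -0.05 and did not pass. Without deleted mouse 11, 9 of the 16 list calls were kept, and those of myofibroblast, glycolysis, tubular injury, T and NK cell, thick limb, collecting duct and immediate early genes ended. Fatty acid oxidation also lost its call without control mouse 10 (0.17, adjusted p = 0.175), immediate early genes without mouse 10 or 12, T and NK cell genes without mouse 9, glycolysis without mouse 8 or 13 and collecting duct genes without mouse 8.

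By the preset camera test the response to obstruction was lower in deleted kidneys of both lines, while the exact test per kidney passed in neither. Of 200 genes that rose most in Snai1-line controls, 175 were lower in Twist1-deleted than in control obstructed kidneys (median -0.43, adjusted p = 7.24e-12, 0.326 with an estimated correlation). Of the 200 that fell most 193 were higher (median 0.80, adjusted p = 1.09e-33). In the Snai1 line, with genes chosen in Twist1-line controls, 197 of 200 rising genes were lower (median -0.67, adjusted p = 5.44e-33). There 199 of 200 falling genes were higher (median 1.00, adjusted p = 8.8e-38). The last 3 sets each had 0.0875 with an estimated correlation. Per kidney, the obstruction score was 1.70 ± 1.67 (SD, n = 4) in Twist1-deleted against 2.98 ± 0.86 (n = 3) in control mice, a difference of -1.28 (exact permutation p = 0.429, smallest possible 0.0286), and 2 of 4 deleted kidneys lay below every control. Mouse 7 had -0.76 and the other 3 deleted mice 2.09, 2.72 and 2.77. Without mouse 7 the difference was -0.46, and without control mouse 2 it was -0.78. In the Snai1 line the score was -0.65 ± 0.87 against 1.12 ± 1.04 (n = 3 and 3), a difference of -1.77, with 3 of 3 deleted kidneys below every control (exact permutation p = 0.1, the smallest possible). In contralateral kidneys the differences were 0.01 (exact permutation p = 1) and -0.07 (exact permutation p = 0.9). By camera both sets were lower there with Snai1 deletion, by medians of -0.12 (rising, 144 of 200 lower) and -0.07 (falling). Their adjusted p was 1.5e-06 and 0.0331, and 0.557 and 0.872 with an estimated correlation. Across genes, the deletion effects of the 2 lines correlated at r = 0.536 (rho 0.464) in obstructed and r = 0.147 (rho 0.121) in contralateral kidneys.

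**Figure D2:**
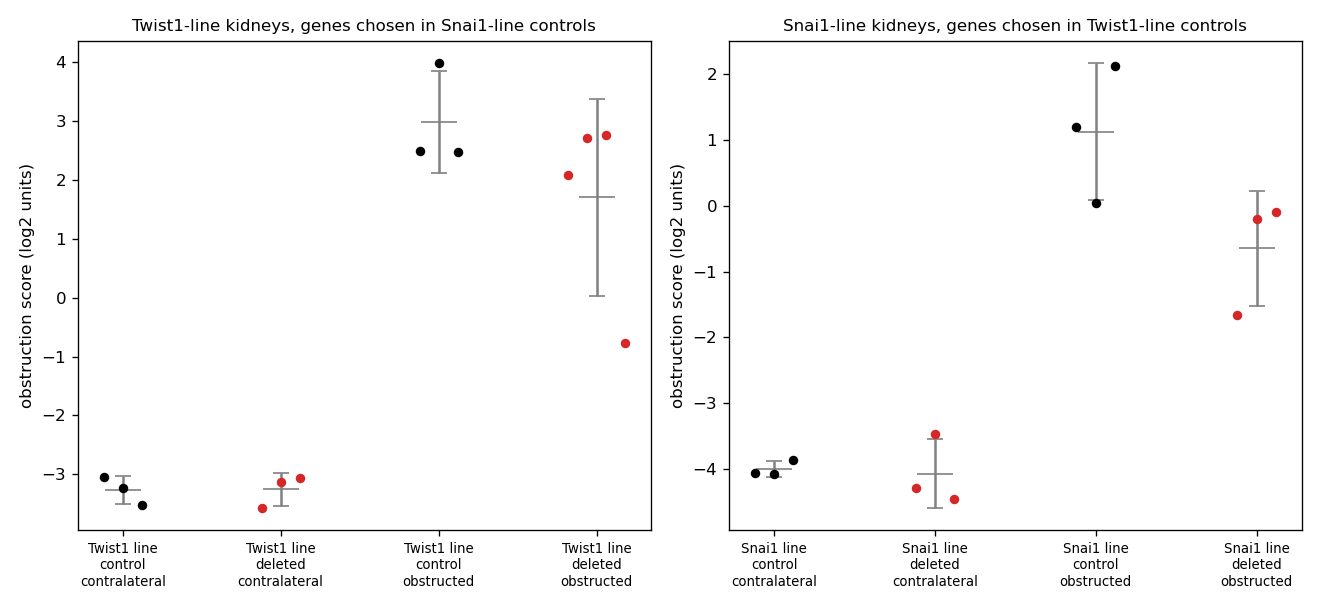
Obstruction score per kidney (vertical axis, log2 units: mean of 200 rising genes minus mean of 200 falling genes chosen in the controls of the other line), with each point a kidney, horizontal lines for means and bars for 1 SD. Among obstructed kidneys the 4 Twist1-deleted ones lay between -0.76 and 2.77 against 2.48 to 3.98 in controls, and the 3 Snai1-deleted ones between -1.65 and -0.09 against 0.04 to 2.12.

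**Figure D3:**
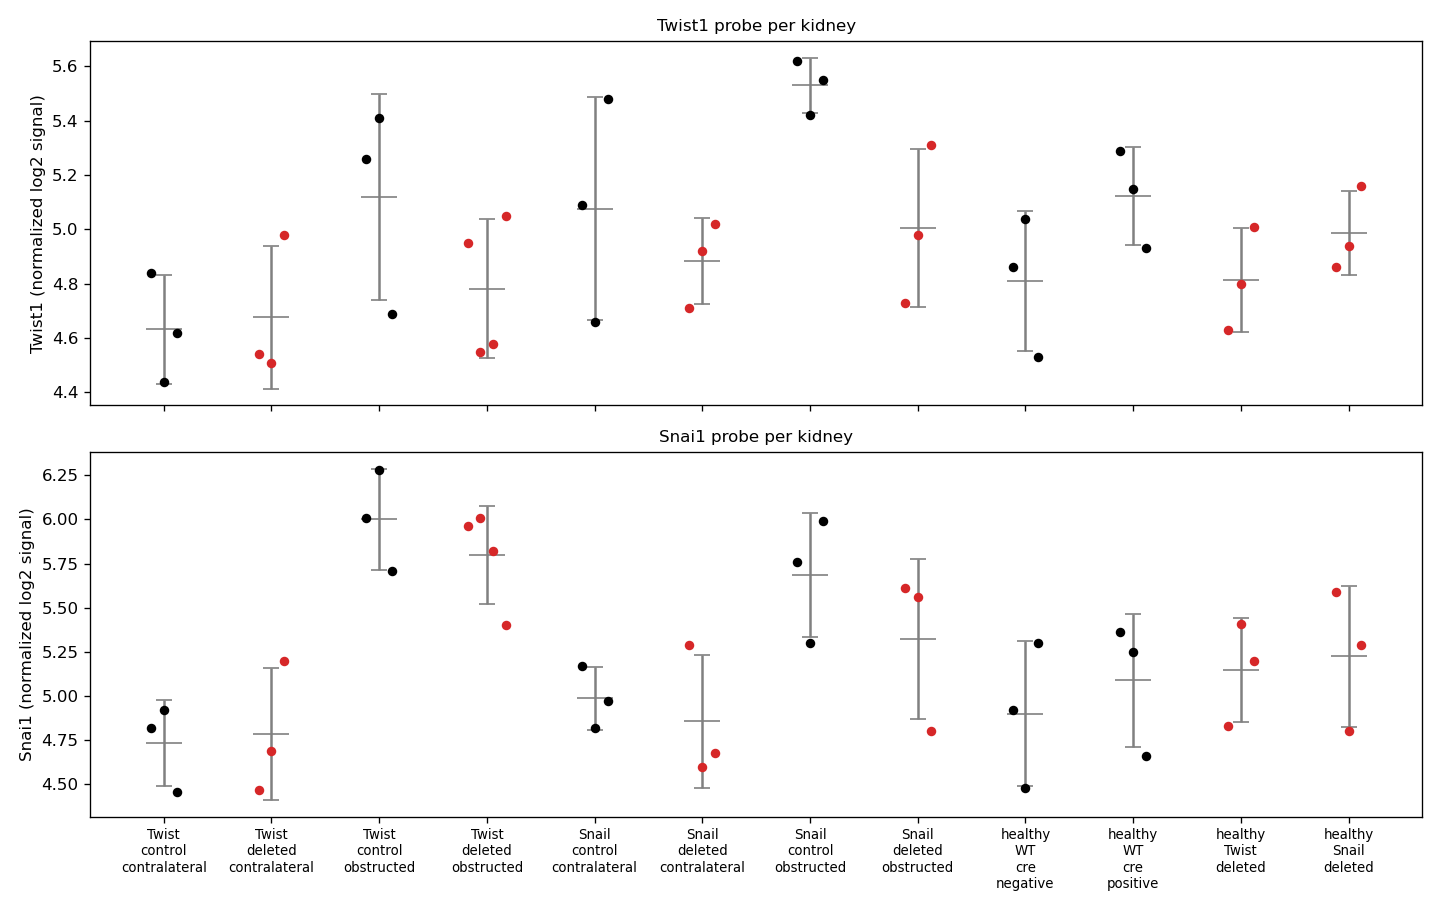
Normalised log2 signal of the Twist1 probe (top) and the Snai1 probe (bottom) in each kidney of the 12 groups, with horizontal lines for means, bars for 1 SD, red points for deleted and black for control or wild-type mice. Snai1 averaged 6 in obstructed and 4.73 in contralateral kidneys of Twist1-line controls.

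Deletion in contralateral kidneys asked whether loss of either gene changes a kidney whose ureter is open. With Twist1 deletion Twist1 differed by 0.04 (adjusted p = 1) and Snai1 by 0.06. Dglucy, a mitochondrial enzyme of D-glutamate, was lower (-0.84, SE 0.14, adjusted p = 0.0261, 4.88 ± 0.34 against 5.72 ± 0.12, n = 3 and 3, detected in 1 of 3 deleted kidneys) and was the 1 gene that passed, with 663 at an unadjusted p under 0.05. Lypd4 (adjusted p = 0.103), the retroviral restriction gene Fv1 (-0.71, adjusted p = 0.105), Gin1 (adjusted p = 0.105) and 2610524H06Rik (1.10, adjusted p = 0.112) did not pass. With 0 members past over all genes or adjusted over the list alone, myofibroblast genes had a median of -0.32 with Rgs5 at -1.11 (adjusted p = 0.00982), immediate early genes -0.41 with Atf3 at -1.43 (adjusted p = 0.00604) and adipose tissue genes -0.77 with Cidec at -1.83 (adjusted p = 0.00692), each with adjusted p = 0.91 with an estimated correlation. With Snai1 deletion Snai1 differed by -0.13 (adjusted p = 1) and Twist1 by -0.19, and by limma 0 genes passed with 328 at an unadjusted p under 0.05. Its smallest p were those of Trp53rka (0.78, adjusted p = 0.513), Trem1, Lrrc57, Wdr47 and Anapc10 (adjusted p = 1). G2 and M phase genes had a median of 0.70 with Prc1 at 1.21 (adjusted p = 1.83e-07, 0.744 with an estimated correlation) and G1 and S phase genes 0.18 with Tyms at 0.60 (adjusted p = 0.00477, 0.89 with an estimated correlation). Macrophage genes had a median of -0.32 with Lyz2 at -0.83 (adjusted p = 1.35e-05, 0.852 with an estimated correlation). Chemokines had -0.24, with Cxcl9 and Cxcl10, attractants of T cells, at -1.72 and -1.12 and 2 of 22 down adjusted over the list alone (adjusted p = 1.35e-05, 0.642 with an estimated correlation). The Twist1 count was 4, 0 or 2 without mouse 1, 3 or 7, and the Snai1 count was 2 without mouse 10. Without mouse 4, 0 of the 3 list calls for Twist1 were kept. Without control mouse 2 adipose tissue genes stood at -0.13 (adjusted p = 0.88), and without control mouse 1 myofibroblast genes at -0.22 (adjusted p = 0.391) and immediate early genes at -0.20 (adjusted p = 0.441). Without mouse 12 the calls of both cell cycle lists for Snai1 ended, with G2 and M phase at 0.20 (adjusted p = 0.289). The macrophage call for Snai1 ended without mouse 8 (-0.12, adjusted p = 0.122), and that of G1 and S phase also without mouse 10 or 11.

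The interaction asked whether deletion changed the response to obstruction itself. For Twist1 deletion, Twist1 had a difference of responses of -0.38 (adjusted p = 0.878) and Snai1 of -0.26 (adjusted p = 0.933). By limma 0 genes passed, with 757 at an unadjusted p under 0.05, and the smallest p belonged to the interferon signalling factor Stat2 (adjusted p = 0.297), Polr3k (-0.84, adjusted p = 0.297), Ccdc15 (-0.98), Sema4f (-0.79) and Ppie (-0.76). Without the contralateral array of mouse 7, 2 genes passed. For Snai1 deletion, Snai1 had -0.23 and Twist1 -0.33 (adjusted p = 1), and by limma 0 genes passed with 408 at an unadjusted p under 0.05, the smallest being Map3k4 (0.71), Zcchc18, Cd209c (-0.86), Dok1 (-1.06) and Tmem19 (0.90) (adjusted p = 1). With the series matrix values the median of all genes shifted by 0.101 in this comparison and by 0.105 for Twist1 deletion in obstructed kidneys. Gene lists differed in 10 cases for Twist1 and 12 for Snai1 by the preset test and in 0 for either with an estimated correlation, and their values stand in the closing section.

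The deletion effects of the 2 lines in obstructed kidneys were also set against each other. Twist1 stood at -0.34 in the Twist1 line and -0.52 in the Snai1 line, and Snai1 at -0.20 and -0.36. By limma 0 genes differed, with 443 at an unadjusted p under 0.05, and the smallest p were those of Stat2 (adjusted p = 0.272), 6330403K07Rik, Ctsl (2.22), Tfip11 and Mill2. Without mouse 7 or mouse 12, 1 gene passed.

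In healthy wild-type kidneys the comparison with and without cre asked what cre alone does. Twist1 differed by 0.32 (adjusted p = 1) and Snai1 by 0.19. Ccng2, an atypical cyclin, was 4.5-fold higher with cre (2.17, SE 0.29, adjusted p = 0.000528, 8 ± 0.40 against 5.83 ± 1, n = 3 and 3), and Aldh1a7, an aldehyde dehydrogenase, was lower (-3.02, adjusted p = 0.0287, 4.95 ± 0.98 against 7.97 ± 0.90) and near background with cre, detected in 1 of 3 kidneys. Bmp2k (-1.08, adjusted p = 0.156), Cpn1 (-2.70, adjusted p = 0.156) and the protease Ctsc (2.23) did not pass, and 306 genes had an unadjusted p under 0.05. By camera 0 of 28 lists passed (smallest adjusted p = 0.247). Without mouse 14, 15 or 16 the count was 1, 5 or 7, and without mouse 18 or 19 it was 5 or 1.

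Twist1 deletion in healthy kidneys, set against wild-type mice with cre, asked what deletion does without injury, in mice that also differed in age (26 against 10 weeks) and in Xist signal. Twist1 differed by -0.31 (adjusted p = 0.43) and Snai1 by 0.06. Hdc, the histamine-forming enzyme, was 168-fold higher (7.39, SE 1.39, adjusted p = 0.00573, 12.87 ± 0.22 against 5.48 ± 0.02, n = 3 and 3) and the growth factor Igf2 70.9-fold higher (6.15, SE 0.88, adjusted p = 0.000335, 12.83 ± 0.53 against 6.68 ± 0.46). Gbp3 (3.81), the efflux pump Abcc3 (3.55), Slpi (3.17), Aldh1a7 (2.80), Cyp2c23 (2.63), Aldh1a1 (2.61), Atp13a4 (at least 3.75-fold) and Pjvk (at least 3.89-fold) were the other largest rises. Ugt2b36 (-4.15), Kif20b (-4.13), Timd2 (-3.80), the phosphatase Ptpn22 (-3.72), Tbx10 (-3.52), Chst7 (-3.50), Ct55 (-3.16), Cyp4a12b (-2.73), Dtd2 (at least 6.83-fold) and Mpped1 (at least 4.68-fold) were the largest falls. In total 436 genes passed, 249 up and 187 down. Of these, 366 had the same sign in contralateral kidneys of Twist1-line controls, which carry no deletion, against wild-type mice without cre, and 143 of them passed there. Aldh1a7 and Cyp2c23 stood low in the wild-type mice with cre (4.95 and 7.65), while those without cre had 7.97 and 9.81 and the deleted mice 7.75 and 10.28. Macrophage genes had a median of 0.50 with 0 of 19 past by either count, over all genes or adjusted over the list alone (adjusted p = 0.0117, 0.934 with an estimated correlation). T and NK cell genes had 0.46 with 0 of 12 over all genes and 6 up adjusted over the list alone, among them Cd3g (0.96) and Nkg7 (1.05) (adjusted p = 0.0439, 0.779 with an estimated correlation). Both list calls ended without mouse 21 (macrophage 0.33, adjusted p = 0.123, and T and NK cell 0.36, adjusted p = 0.0976), and the T and NK cell call also without mouse 14 or 15. Sex-dimorphic kidney genes had a median of -1.34, with 1 of 13 down over all genes and 2 up and 7 down adjusted over the list alone, where Cyp4a14 stood at 5.80 and Cyp2j13 at -6.79 (adjusted p = 0.0579). The count was 127, 117 or 64 without mouse 14, 15 or 16 and 148, 84 or 112 without mouse 20, 21 or 22, and with the covariate of Y-linked minus Xist signal it was 20. Without both kidneys of mouse 7, in another group, it was 954. With the series matrix values 958 passed, 67.8% of them higher against 57.1%.

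Snai1 deletion in healthy kidneys was read in the same way, against the same wild-type mice and with the same age gap. Line went with deletion here, since the labelled background of the Snai1 line (Balb/c in place of sv129) differs from that of the wild-type mice. Snai1 differed by 0.14 (adjusted p = 0.952) and Twist1 by -0.14. Tomm22, a mitochondrial import receptor, was 13.8-fold higher (3.78, SE 0.26, adjusted p = 1.49e-10, 10.57 ± 0.01 against 6.79 ± 0.07, n = 3 and 3) and Pdrg1 at least 24-fold higher (adjusted p = 0.00175). The vitamin D activating enzyme Cyp27b1 was 5.7-fold higher (adjusted p = 0.0465) and the cell cycle inhibitor Cdkn1a 4.93-fold higher (adjusted p = 0.00661). Aldh1a7 (3.67, detected in 1 of 3 wild-type kidneys), Cpn1 (3.25), Cyp2c23 (3.04), Mettl14 (2.53), Csrnp1 and Tm7sf3 (at least 9.25-fold) were also higher. Ptpn22 (-3.47), Chmp1a (-2.44), the heat shock gene Hspa1a (-2.31), Prxl2b (-2.22), Adat2 (-1.97), the histone genes H4c8 (-1.86) and H4c12 (-1.75), Zcchc3 (at least 3.14-fold), Ubxn10 (at least 2.52-fold) and Cmss1 (at least 2.82-fold) were lower. Snai1-line controls, which carry no deletion, had similar levels of Tomm22 (9.54 to 10.53) and Pdrg1 (9.34 to 9.90). Aldh1a7, Cpn1 and Cyp2c23 stood low in the wild-type mice with cre (4.95, 8.16 and 7.65), while those without cre had 7.97, 10.87 and 9.81 and the deleted mice 8.62, 11.42 and 10.70. In total 112 genes passed, 72 up and 40 down, and 0 of 28 lists did by camera (smallest adjusted p = 0.366). Of the 112, 90 had the same sign in contralateral kidneys of Snai1-line controls against wild-type mice without cre, and 27 of them passed there, so this comparison does not separate deletion from line. The count was 63, 74 or 71 without mouse 14, 15 or 16 and 72, 46 or 52 without mouse 23, 24 or 25. With the series matrix values 400 passed, 53.5% of them higher against 64.3%.

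Contralateral kidneys of Twist1-line controls, set against healthy wild-type kidneys without cre, asked whether the untouched kidney of an obstructed mouse can stand for a healthy one. Twist1 differed by -0.18 and Snai1 by -0.17. The amino acid oxidase Dao was higher by 5.25, but ranged widely among healthy kidneys (6.69 ± 3.53, n = 3), and another of its probes passed with the opposite sign. Pdrg1 (at least 10.4-fold), Ctsc (3.23), Dctn1 (at least 5.59-fold), Adgrf5 (2.86), Arl2bp (2.83), the angiotensin precursor Agt (2.67), Prcp (2.40), Tmem63b (2.35) and Trim7 (at least 3.21-fold) were higher. H2-Ea, an antigen-presenting class II chain, was at least 39.1-fold lower (adjusted p = 0.00572), followed by Nudt6 (-4.11), Abhd1 (-3.99), the globin Hbb-b2 (at least 9.1-fold), Dtd2 (at least 6.26-fold), Serpina3b (-3.23), Chmp1a (at least 6.07-fold), Atp10d (-2.48), Rtn4 (-2.43) and Ang (-2.35). In total 2281 genes passed (17.7%), 1104 up and 1177 down, and 0 of 28 lists did by camera (smallest adjusted p = 0.142). Without healthy mouse 18 or 19 the count was 1441 or 1406. With the series matrix values 3293 passed, 12.4% of them higher against 48.4%, and the median of all genes shifted by -0.333.

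In lists that did not pass, the median, mean and test also differed in sign in other comparisons. With Snai1 deletion these were epithelial junctions in obstructed kidneys and mesenchymal transition and thick limb genes in contralateral kidneys. For the Twist1 interaction they were collecting duct, immediate early and blood genes, and for the contrast of the lines epithelial junctions, G1 and S phase, p53 targets, podocyte, thick limb and immediate early genes. In healthy kidneys they were tubular injury, G2 and M phase and blood genes for cre, fatty acid oxidation for Twist1 deletion, and mesenchymal transition, proximal tubule enzyme, tubular injury, chemokine, collecting duct and blood genes for Snai1 deletion. For contralateral against healthy kidneys they were mesenchymal transition, epithelial junction, proximal tubule transporter and neutrophil genes.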

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

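The tests of a single mouse and of the Y-linked minus Xist signal for the obstruction score, and the score over both lines, were chosen after the result was seen, whereas the test of a milder course of obstruction and the other splits of the samples were planned.

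Mouse 7 stood apart from the other 3 Twist1-deleted obstructed kidneys. Its mean log2 level was 7.42 for myofibroblast and pericyte genes, 11.87 for mitochondrial respiration, 9.20 for tubular injury, 7.35 for chemokines and cytokines and 8.20 for the TGF-beta pathway. The Y-linked minus Xist signal of this kidney was -2.82, and its values on principal components 2 and 3 were -14.6 and 26.0. Mouse 4 stood apart in the same group for G2 and M phase genes, at 7.00. Of 38 measures tested by Dixon's ratio in this group 9 passed, 8 of them through mouse 7, where chance flags about 1 in 20 groups.

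The response to obstruction differed between Twist1-deleted and control mice for 10 gene lists by the preset camera test of the interaction, with 0 members past the threshold over all genes. Transporters of the proximal tubule had a median difference of 0.82 (adjusted p = 7.91e-09, 0.229 with an estimated correlation) and its enzymes 1.09 (adjusted p = 4.19e-08, 0.229 with an estimated correlation). Fatty acid oxidation genes had 0.52 (adjusted p = 1.25e-09, 0.198 with an estimated correlation), mitochondrial respiration genes 0.26 (adjusted p = 1.63e-06, 0.691 with an estimated correlation), and thick limb and distal tubule genes 0.57 (adjusted p = 0.0066, 0.778 with an estimated correlation). Adipose tissue genes had 2.71 (adjusted p = 5.88e-07, 0.198 with an estimated correlation). Matrix genes had -0.22 (adjusted p = 0.0395) and G1 and S phase genes -0.26 (adjusted p = 0.0428). Both had 0.803 with an estimated correlation. Macrophage genes had -0.33 (adjusted p = 0.0066) and chemokines -0.32 (adjusted p = 0.0423). Both had 0.778 with an estimated correlation. Adjusted over the list alone, 1 thick limb gene and 1 adipose gene passed. Without both kidneys of mouse 7, the calls of matrix (0.06, adjusted p = 0.84), G1 and S phase, macrophage, chemokine and thick limb genes ended. The 5 kept calls had medians of 0.54 for transporters, 0.65 for enzymes, 0.33 for fatty acid oxidation, 0.16 for respiration and 2.79 for adipose tissue. Without the obstructed kidney of mouse 7 alone, respiration ended (0.07, adjusted p = 0.22) and G1 and S phase was kept.

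The same test for Snai1 deletion found 12 lists, with 0 members past over all genes and 0 adjusted over the list alone. Medians were 0.94 for proximal tubule transporters (adjusted p = 2.32e-10) and 0.97 for its enzymes (adjusted p = 8.03e-08). Both had 0.418 with an estimated correlation. Fatty acid oxidation stood at 0.34 (adjusted p = 3.7e-05), respiration at 0.34 (adjusted p = 8.03e-08), mesenchymal transition genes at -0.33 (adjusted p = 0.00345) and G2 and M phase genes at -0.95 (adjusted p = 5.91e-06), each with adjusted p = 0.454 with an estimated correlation. Matrix genes had -0.61 (adjusted p = 8.08e-06, 0.546 with an estimated correlation) and TGF-beta pathway genes -0.33 (adjusted p = 0.00301, 0.502 with an estimated correlation). Tubular injury genes had -0.37 (adjusted p = 0.0239), G1 and S phase genes -0.34 (adjusted p = 0.00301) and thick limb genes 0.47 (adjusted p = 0.00231), each with adjusted p = 0.633 with an estimated correlation, and macrophage genes -0.21 (adjusted p = 0.044, 0.642 with an estimated correlation). Most of the G2 and M phase difference came from contralateral kidneys, where Snai1 deletion gave a median of 0.70 against -0.20 in obstructed kidneys, with Prc1 at 1.21 and -0.32. Without the contralateral kidney of mouse 12 the median there was 0.20 (adjusted p = 0.289). The calls of G1 and S phase, tubular injury, macrophage and TGF-beta pathway genes each ended without 1 or more single arrays.

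Between the lines, the deletion effect in obstructed kidneys differed for 4 lists, with 0 members past by either count. Twist1 minus Snai1 deletion gave 0.23 for matrix and 0.25 for fatty acid oxidation (both adjusted p = 0.0166). Macrophage genes had 0.31 (adjusted p = 0.0177) and adipose tissue genes 1.53 (adjusted p = 0.0141). All had 0.979 with an estimated correlation. All 4 depended on single kidneys. Matrix stood at 0 (adjusted p = 0.625) without mouse 11, 0.03 without mouse 3 and 0.54 without mouse 7. Macrophage genes had 0.15 (adjusted p = 0.453) without mouse 8. Without both kidneys of mouse 7 fatty acid oxidation had 0.07 (adjusted p = 0.563) and adipose tissue 1.42 (adjusted p = 0.0509). This fit gained 8 lists, and that without mouse 2 gained 11.

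Other splits of the mice were counted. For the Twist1 interaction 21 of 35 splits gave as many lists (10, highest other 18). For the contrast of the lines 94 of 100 drawn splits did (4, highest other 20). Chance is thus not excluded for these lists. The real gene count was 0 in both, which any split reaches (highest other 11 and 425), so it cannot decide. Splits that call up to 425 genes point to a structure of the samples. For the Snai1 interaction 10 splits are too few for a share under 0.05, with 12 lists against a highest other of 15 and 0 genes against 0.

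The lower obstruction score of deleted kidneys was weighed against 3 explanations. In the Twist1 line 1 mouse is a candidate explanation, since the difference went from -1.28 to -0.46 without mouse 7, whereas in the Snai1 line the smallest difference with 1 kidney left out was -1.27 against -1.77, which argues against it. Mouse 7 also differed from mice 1 to 6 in H2-Ea, H2-K1, Pdrg1 and Hbb-b2, so its label or breeding, and the Twist1 results that depend on it, stay open. With a covariate of Y-linked minus Xist signal the differences were -1.30 and -1.77, which argues against sex as the cause in either line. A milder course of obstruction that is independent of genotype stays open, since across genes the deletion effects ran against the obstruction effect of the other line at r = -0.564 and r = -0.75, which loss of Twist1 or Snai1 would also give, so the explanations cannot be told apart. Over both lines the mean difference was -1.52 (7 against 6 kidneys, exact stratified permutation p = 0.0471 over 700 reassignments), and without mouse 7 it was -1.11 (exact permutation p = 0.075 over 400). The Twist1-line part of both means carries the limit given above for mice 2 and 7.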

How the results depend on the processing

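Alternatives without mouse 7, with the signal floor as covariate, with Snai1-line contralateral kidneys and with the mean of both lines were chosen after seeing the data, and the others were planned. Both obstruction counts stayed within 1.5 times their value under every alternative run, and no called gene list changed the sign of its median under the 3 other scalings (101 calls, 303 values, 0 turned). The estimated inter-gene correlation ended all calls, with 0 list shifts and 0 signature shifts left. For single lists in the 4 comparisons of obstruction and of deletion in obstructed kidneys, 5 of 336, 3 of 336, 36 of 364 and 14 of 336 values fell below the threshold, 19, 3, 21 and 9 came above it, 0 reversed, and the rest kept their direction and side. The stricter detection filter and signatures of 50 or 500 genes moved none of these counts beyond 1.5 times.

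Counts of genes that moved are given by setting, and the cause was not tested except where the setting changes which arrays or genes are fitted. Quantile normalisation without a background step gave 8 genes for Twist1 and 2 for Snai1 deletion in obstructed kidneys, 0 for Twist1 deletion in contralateral kidneys, 1 for the contrast of the lines and 1 for cre (higher). An offset of 50 gave 13 and 3 for Twist1 and Snai1 deletion in obstructed kidneys and 1 for cre (higher). The series matrix values gave 2 for Twist1 deletion in obstructed kidneys (1 higher), 1 for Snai1 deletion in contralateral kidneys, 2 for the Twist1 interaction, 1 for the contrast of the lines, 958 and 400 for Twist1 and Snai1 deletion in healthy kidneys, and for Twist1 deletion in contralateral kidneys 1 gene, higher in place of lower. No detection filter gave 2 for Twist1 deletion in obstructed kidneys, 6 in contralateral kidneys and 1 for its interaction. All kept probes gave 1 for Snai1 deletion in obstructed and 2 for Twist1 deletion in contralateral kidneys. The covariate of Y-linked minus Xist signal gave 7 and 5 for Twist1 and Snai1 deletion in obstructed kidneys, 2 for Twist1 deletion in contralateral kidneys and 20 in healthy kidneys, 19 of them among the 436. A fit of only the compared groups gave 0 for Twist1 deletion in obstructed kidneys, 1 for cre, and 2142 and 419 for Twist1 and Snai1 deletion in healthy kidneys. Both wild-type groups as control gave 780 and 242 for the healthy deletions. Mouse as a random replicate block gave 1 gene for the Twist1 interaction.

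Without both kidneys of mouse 7 the counts were 2 and 73 for Twist1 and Snai1 deletion in obstructed kidneys, 3 for Twist1 deletion in contralateral kidneys, 2 for its interaction, 2 for the contrast of the lines, 1 for cre, and 954 and 207 for Twist1 and Snai1 deletion in healthy kidneys. The floor covariate gave 2 and 1 for Twist1 and Snai1 deletion in obstructed kidneys and 206 for contralateral against healthy kidneys, 182 of them among the 2281. Contralateral kidneys of Snai1-line controls against the healthy group gave 57 genes, and the mean deletion effect of both lines 169.

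Leaving out each array in turn gave 5309 to 5848 genes for obstruction in the Twist1 line and 3460 to 4448 in the Snai1 line. Deletion gave 0 to 83 for Twist1 and 0 to 5 for Snai1 in obstructed kidneys, 0 to 4 and 0 to 2 in contralateral kidneys, and 64 to 148 and 46 to 74 in healthy kidneys. The interactions gave 0 to 2 and 0 to 0, the contrast of the lines 0 to 1, cre 1 to 7 and contralateral against healthy kidneys 1406 to 1709. List shifts ranged from 90 to 114, signature shifts from 5 to 7 and named genes from 87 to 109. The score differences ranged from -1.63 to -0.46 and from -2.31 to -1.27 in obstructed kidneys, and from -0.11 to 0.18 and from -0.37 to 0.12 in contralateral kidneys. Of the obstruction lists, endothelial and sex-dimorphic genes lost their call without mouse 2, immediate early genes without mouse 3, collecting duct genes without mouse 8 and G1 and S phase genes without mouse 10.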

Other observations

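The tests of the signal floor and of line or strain background, the choice of genes that tell the lines apart, and the mean deletion effect of both lines with its splits were chosen after the result was seen. The test in contralateral kidneys of the Snai1 line was added after seeing the data, and its prediction, like those of the other tests, was written before its result.

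Averaged over both lines, deletion in obstructed kidneys gave more genes than either line did alone, 169 past the threshold by limma (100 up and 69 down, 2437 at an unadjusted p under 0.05). Among the named genes, chosen after their values were seen, the largest rises were those of the nuclease Dnase1 (2.08), the carboxylesterase Ces1d (2.05), the dicarboxylate transporter Slc13a3 (1.89, adjusted p = 0.0277), the inositol-degrading enzyme Miox (1.88), the gluconeogenic G6pc (1.77) and the glucose transporter Slc5a2 (1.59, adjusted p = 0.0259). Hnf4a, a transcription factor of proximal tubule identity, rose by 0.82 (adjusted p = 0.0206). The largest falls were those of the sugar transporter Slc2a6 (-1.53, SE 0.24, adjusted p = 0.00687), Scara3 (-1.42), the p53 target Rprm (-1.19) and Ccdc80 (-1.16). Proximal tubule transporters had 5 of 24 members up over all genes and 19 adjusted over the list alone (median 0.90, adjusted p = 4.92e-15, 0.132 with an estimated correlation), and mitochondrial respiration genes 1 of 24 and 20 adjusted over the list alone (median 0.32, adjusted p = 1.24e-13, 0.132 with an estimated correlation). Matrix genes had 0 of 25 over all genes and 10 down adjusted over the list alone (median -0.53, adjusted p = 1.9e-09, 0.208 with an estimated correlation). Macrophage (-0.47, adjusted p = 1.51e-06), chemokine (-0.47, adjusted p = 3.56e-06), T and NK cell (-0.32, adjusted p = 0.00409) and immediate early and handling genes (-0.33, adjusted p = 0.0206) stood lower. So did myofibroblast, mesenchymal transition, tubular injury and TGF-beta genes by the preset test. Proximal tubule enzymes, fatty acid oxidation, thick limb and collecting duct genes also stood higher. With an estimated correlation these lists had adjusted p of 0.132 to 0.381. Sex-dimorphic kidney genes (1.16, adjusted p = 0.0168) and adipose tissue genes (0.66, adjusted p = 0.0463) moved the same way as the transporters (0.249 and 0.388 with an estimated correlation).

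This count depended on single kidneys and on the scaling. Without both kidneys of mouse 7 it was 25, and without the obstructed kidney of control mouse 2, 3, 8, 9 or 10 it was 23 (6 up and 17 down), 660, 20 (8 up and 12 down), 501 or 1. Without that of control mouse 1, 205 genes were higher and 109 lower. Without that of deleted mouse 5, 6, 7, 11 or 12 it was 561, 540, 22, 0 or 268. The balance turned with quantile normalisation without a background step (143 up and 190 down) and with an offset of 50 (162 up and 180 down), and the series matrix values gave 1 gene. Of 100 drawn splits 5 gave as many genes, with a highest other of 598, so chance is not excluded, and splits with several times the real count point to a structure of the samples.

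Genes with an on-or-off signal, chosen after their values were seen, told the mice apart in a way the labels do not. H2-Ea, a class II gene that is silent in the b haplotype carried by C57BL/6, lay at 4.41 to 4.47 in Twist1-line controls and 4.41 to 4.81 in Twist1-deleted mice 4 to 6. In mouse 7 it lay at 11.24 to 12.89, in the Snai1 line at 10.05 to 14.11, in wild-type mice at 9.68 to 10.73, in healthy Twist1-deleted mice at 10.60 to 10.97 and in healthy Snai1-deleted mice at 11.08 to 11.58. H2-K1 followed, at 5.49 to 6.93 in mice 1 to 6, 9.09 to 10.19 in mouse 7 and 8.37 to 8.83 in healthy Twist1-deleted mice. Pdrg1 lay at 8.29 to 8.98 in mice 1 to 6, at 4.41 to 4.53 in mouse 7, at 4.31 to 4.48 in wild-type mice and at 4.64 to 8.84 in healthy Twist1-deleted mice. Hbb-b2 lay at 8.59 to 9.96 in mouse 7 and at most at 4.81 in mice 1 to 6. Dtd2 did not part mouse 7 from mice 1 to 6, with 4.26 to 4.35 against 4.27 to 4.43. Tomm22 lay at 9.54 to 10.59 in the Snai1 line and the healthy Snai1-deleted mice and at most at 7.04 in all other mice. Both kidneys of mouse 7 gave the same reading for each of these genes.

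The genes that differed between contralateral kidneys of Twist1-line controls and healthy wild-type kidneys were weighed against 3 explanations. Obstruction of the other kidney as the cause is argued against, since the median change of the 2281 genes, signed by direction, was 0.75 in the Twist1 line, 0.68 against the other wild-type group and 0.069 in contralateral kidneys of the Snai1 line, where 64.5% had the same sign. A floor covariate cannot decide whether a low signal floor is the whole cause. The floors of the groups do not overlap (88.3 to 95.9 against 107.6 to 112.5). With the covariate the median was 0.53 (median SE 0.26, before 0.20) and 206 genes passed. Line or strain background is a candidate explanation, since the same genes differed by 0.49 between obstructed control kidneys of the 2 lines, whose arrays have like floors. Whether strain, housing or the day of handling lies behind the line difference was not tested.

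For the genes changed in healthy Twist1-deleted kidneys 2 explanations were weighed. Sex may account for much of the pattern, since across the 436 genes the change correlated at r = -0.827 with the coefficient of the Y-linked minus Xist signal in the other arrays, and 374 genes (85.8%) had the sign it predicts. For the 112 genes of healthy Snai1-deleted kidneys the same value was r = 0.025, with 50 genes of the predicted sign. Age stays open, since the 436 genes correlated at r = 0.174 with the change in Snai1-deleted mice of the same age against the other wild-type group, too near the bound of 0.2 set before to decide. Deletion of Twist1 itself was not told apart from sex, age or line by this design.

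Other splits of the mice were counted for each comparison. Where 3 arrays faced 3, 10 splits are too few for a share under 0.05, and the real count and the highest other were 6063 and 29 genes for obstruction in the Twist1 line, 4673 and 1 in the Snai1 line, 0 and 2 for Snai1 deletion in obstructed kidneys, 1 and 7 for Twist1 and 0 and 2 for Snai1 deletion in contralateral kidneys. They were 2 and 4 for cre, 436 and 6 for Twist1 deletion and 112 and 1 for Snai1 deletion in healthy kidneys, and 2281 and 2 for contralateral against healthy kidneys. Among the 4 splits that parted all 3 pairs of an obstruction comparison, the other 3 gave 0 genes each in either line. For gene lists the real count and the highest other were, in the same order, 19 and 20, 17 and 17, 16 and 14, 3 and 5, 4 and 6, 0 and 3, 2 and 6, 0 and 2, and 0 and 6. For Twist1 deletion in obstructed kidneys 18 of 35 splits gave as many genes (4, highest other 140), so chance is not excluded. The splits that set mice 2, 3, 5 and 6 or mice 1, 3, 4 and 7 against the rest gave 140 and 116 genes, which points to a structure of the samples.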
